A study of Arabidopsis thaliana with 12 samples.

How the data were processed

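RNA-seq was measured in 6 libraries from 21-day seedlings grown on soil, 3 of wild-type Col-0 and 3 of the xrn3-8 mutant. Small RNA-seq was measured in 6 libraries from 14-day seedlings grown on MS plates, again 3 per genotype. The series' design text calls the replicates biological. The RNA-seq libraries were stranded, ribosomal-RNA-depleted total RNA libraries, per the labels' protocols. Every deposited table holds whole-number read counts per feature, made by the authors and not normalized. HISAT2, HTSeq, DESeq2 and bedtools are named for RNA-seq, and Bowtie, HTSeq, DESeq2 and bedtools for small RNA, with the TAIR10 build, per the submitters' processing notes. Their versions and settings are not given in the sources used here.

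Each RNA-seq library came with counts for 37184 annotated genes and 9585 assembled loci, whose identifiers start with XLOC. A second table held 33985 windows, each named 500 plus a gene identifier, counted together with the genes. The side of the gene on which a window lies is not given in the sources used here, so the windows are called flanking windows. Each small RNA library came with counts for the same genes and for 3206 of the assembled loci in a table named xat. The meaning of that name and the rule that picked those loci are not given in the sources used here. All 2161 of them that could be tested were higher in xrn3-8 RNA-seq, with log2 fold changes of 1.18 or more. They therefore carry a choice that appears to have been made on these RNA-seq libraries, and their direction there is not independent evidence.

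Counter tallies for unassigned reads were left out of library sizes and tests. They held 22.6% to 26.1% of the tallied RNA-seq reads and 74.6% to 77.1% of the small RNA reads. In the small RNA tables the tally of reads with several positions is 0 and some loci hold identical counts. Small RNA reads with several positions appear to have been counted at each of them, but how they were handled is not given in the sources used here. Small RNA values of repeated loci may therefore not be independent. Whether the counting used the strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart. Near-identical gene copies such as the LHCB1, LHCB2 and RBCS genes are uncertain for the same kind of reason.

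Names, gene classes and gene order came from a reference table of the TAIR10.1 assembly, which matched 36899 of the 37184 identifiers. This reference has no separate class for transposable elements, so whether its pseudogenes include them cannot be told. It gives no strand, and none of its coordinates is printed. The planned test of tandem and convergent neighbours needs a strand and was not run. A strand-free form took its place, comparing each window with the genes on either side of its own gene. The gap between the genes was 500 to 2000 nt. The planned match of xat loci to windows needs locus coordinates and was not run. Loci tested in both assays were compared instead.

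Counts were tested with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, separately for each assay. The filter was filterByExpr with a minimum count of 10, and scaling used TMM factors. Windows and assembled loci were scaled by the RNA-seq gene table, and xat loci by the small RNA gene table, so that a general change in them was kept. The window-to-gene ratio was the interaction of region and genotype with the library as a block, for windows that passed the filter and genes with a mean count of at least 10. Every adjusted p below comes from edgeR unless another test is named. The standard error of a log2 fold change was its size divided by the square root of the quasi-likelihood F. CPM values, scaled counts per 1e+06, use the scaled library sizes and are means ± SD over 3 libraries. Where a group had 0 counts, the fold was bounded with a floor of 3 counts over the group. With 1 to 3 counts, the ratio of scaled counts is given with an exact 95% interval. Intervals and floors cover counting error only.

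Before the data were examined, 18 gene lists with 265 members were fixed. Of these members, 224 were in the tables, and 3 were left out because the reference names their identifiers otherwise (RRP45B, MTR3 and CFIS1). The 8 TAS loci and 33 MIR genes are not analysed here. The lists cover the XRN family with FRY1, nuclear exosome, 3′ end processing, RNA silencing, photosynthesis, cold with drought and abscisic acid, salicylate, jasmonate, heat shock, circadian clock, phosphate starvation, flowering time, root, flower and seed, dividing-cell and senescence genes. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry. The rule for named genes took the 10 largest positive and 10 largest negative log2 fold changes past the threshold per test, with a mean of at least 1 CPM and no overlap between the groups. For window-to-gene ratios the mean CPM was that of the gene and the overlap that of the ratios, so windows named there may lie under 1 CPM or overlap in their own CPM. For small RNA over genes it took 5 and 5. It added XRN2, XRN3, XRN4 and FRY1, up to 4 members of each list with the smallest adjusted p, and up to 5 neighbouring pairs. Of the assembled loci at most 2 that rose and 2 that fell are printed. Not every feature the rule took is printed. Genes named beyond this rule were chosen after their values were seen. The fits of assembled loci, the tests of gene classes, the strand-free neighbour test and the comparison of loci between assays were also chosen after the data were seen.

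Each test was first run on simulated counts drawn from the real means, dispersions and library sizes, with 200 changed features. Among 20595 simulated genes, 76.8% of the 2-fold and 97.0% of the 4-fold changes were recovered. Among 2774 simulated windows the shares were 23.6% and 84.4%, and among 2612 simulated window-to-gene ratios 9.64% and 75.9%. Among 8903 small RNA genes they were 38.9% and 78.6%, among 761 xat loci 81.1% and 97.9%, and among 5122 assembled loci 26.4% and 75.3%. False calls were 18 of 190 calls for genes, 4 of 106 for windows, 2 of 73 for ratios, 5 of 119 for small RNA genes, 8 of 180 for xat loci and 5 of 99 for assembled loci. Each test called more features in the real data than in its simulation. The adjusted threshold there was less strict, so the simulated shares may understate recovery. Alternatives covered DESeq2, other scaling, no filter, a block on the replicate number, and each library left out in turn. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and, for plots, matplotlib 3.10.9. Pairs of libraries of the same group differed by more than sampling noise, with chi-square values per degree of freedom of 5.44 or more. In RNA-seq they lay at 14.7 to 16.2 in Col-0 and at 35.5 to 70.7 in xrn3-8. In small RNA they lay at 5.44 to 19.5 in Col-0. There xrn3-8 replicates 1 and 2 gave 22.0, while replicate 3 gave 193.5 with replicate 1 and 159.7 with replicate 2.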

Results

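The series compared Arabidopsis thaliana Col-0 with xrn3-8, a mutant of XRN3, a nuclear 5′-to-3′ exoribonuclease. Its title names transcription termination by XRN3 and the expression of protein-coding genes as the question. RNA-seq gene counts per library lay between 61604670 and 79845518 over 6 libraries, 3 per genotype. Chloroplast genes held 52.4% ± 0.48 of these counts in Col-0 and 52.3% ± 2.23 in xrn3-8 (SD, n = 3). Small RNA counts over genes lay between 5873199 and 7122245 over 6 other libraries, 3 per genotype. The 2 assays used seedlings of different age and medium, so no library of one is paired with a library of the other.

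XRN3 RNA (AT1G75660) was 2.38-fold lower in xrn3-8, while small RNA over the same gene was higher by a log2 fold change of 10.28 (SE 0.77, adjusted p = 0.00036). Its RNA-seq level was 48.8 ± 0.21 CPM in Col-0 and 20.5 ± 1.33 CPM in xrn3-8 (SD, n = 3), a log2 fold change of -1.25 (SE 0.08, adjusted p = 2.8e-06). The RNA of XRN3 was thus lowered and not lost. Small RNA counts over XRN3 were 276, 790 and 350 in Col-0 and 538823, 573638 and 706264 in xrn3-8. They made up 0.00734% ± 0.0041 of the small RNA counts over genes in Col-0 and 8.93% ± 1.27 in xrn3-8. Col-0 replicate 2 held 790 of the 1416 Col-0 counts, and the log2 fold change of XRN3 small RNA was 10.90 without it (adjusted p = 0.0022). Of the related exoribonucleases, the nuclear XRN2 (AT5G42540) had an RNA-seq log2 fold change of -0.06 (SE 0.07, adjusted p = 0.55). The cytoplasmic XRN4 (AT1G54490) had 0.09 (SE 0.08, adjusted p = 0.38). With total counts in place of TMM factors, which moved the median of all genes by 0.16, XRN2 stood at 0.09 and XRN4 at 0.25 (adjusted p = 0.041). FRY1 (AT5G63980, named SAL1 in the reference), a phosphatase that removes an inhibitor of XRN enzymes, fell from 35.6 ± 1.62 to 22.6 ± 1.11 CPM (adjusted p = 0.00013). The flanking window of XRN3 held 4, 2 and 6 counts in Col-0 and 10, 12 and 18 in xrn3-8, too few for a test.

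**Figure D1:**
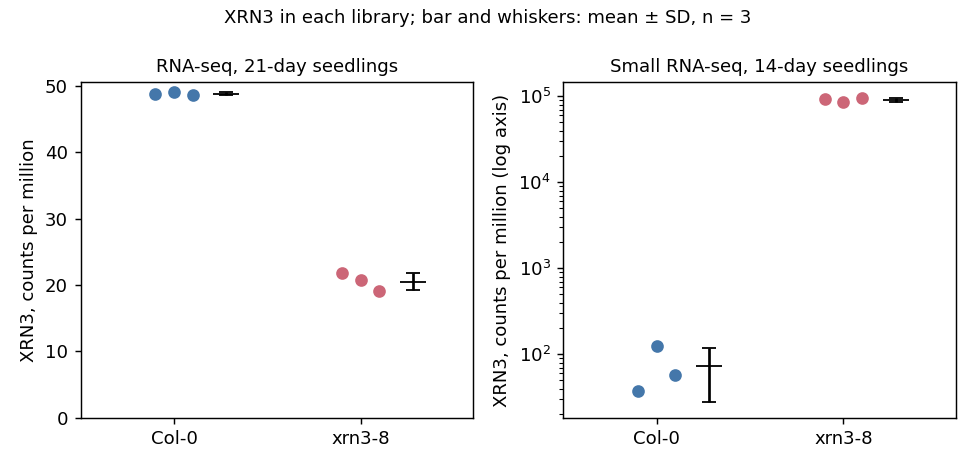
XRN3 in CPM in each library, RNA-seq on a linear axis (left) and small RNA-seq on a log axis (right); points are libraries, and the bar with whiskers is the mean ± SD of 3. RNA lies near 48.8 in Col-0 and 20.5 in xrn3-8, while small RNA lies between 37.8 and 125 in the Col-0 libraries and between 85592 and 95268 in the xrn3-8 libraries.

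Reads in the windows that flank genes were more abundant in xrn3-8. They amounted to 0.177% ± 0.0073 of gene counts in Col-0 and 0.349% ± 0.042 in xrn3-8, with no overlap between the groups (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 can give). Of 2925 windows tested, 1441 were higher and 47 lower in xrn3-8, and the median log2 fold change was 1.05. The window of GRP7 (AT2G21660), a clock-regulated RNA-binding protein, rose from 2 to 755 counts over the group, a ratio of 320 (95% interval 88.3 to 2646). Both Col-0 counts lay in Col-0 replicate 2, and its log2 fold change of 8.09 was 10.87 without that library. That of CAF1a (AT3G44260), a deadenylase, rose from 2 to 509 counts, a ratio of 216 (59.4 to 1786). The window of AT1G07135 held 0 counts in Col-0 and 736 in xrn3-8, at least 208-fold higher. The windows of the metallothionein MT2A, the heat shock cognate HSC70-1 and the dehydrin ERD10 rose by log2 fold changes of 6.60 (SE 0.44), 6.33 (SE 0.37) and 6.18 (SE 0.47). The window of WRKY70, a defence transcription factor, rose by 6.62 (SE 0.52) and those of TEM1, RAP2.4 and EXL2 by 6.58, 5.98 and 5.90. The 5 Col-0 counts of the WRKY70 window all came from Col-0 replicate 1, without which its fitted log2 fold change was 10.60. With 1 Col-0 library left out, the windows of MT2A, TEM1, RAP2.4 and ERD10 reached 7.26, 7.23, 6.89 and 7.77. The strongest falls were those of AT3G06655 (-2.58, SE 0.20), AT4G04409 (-2.14, SE 0.29) and the window of the ubiquitin ligase gene PUB24 (-1.81, SE 0.25). Windows of small nuclear RNA genes, the RNAs of the spliceosome, were higher for 5 of 5 tested. When windows were scaled on themselves instead of on genes, 671 were higher and 347 lower (65.9% instead of 96.8% of calls higher), which removes a shift common to the windows by construction. DESeq2 with its own size factors gave 911 higher and 246 lower (78.7%).

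Window counts also rose relative to the genes they flank. In the ratio of window to gene, 1407 of 2752 pairs were higher and 11 lower in xrn3-8. The 10 largest rises that the rule took had no window counts in Col-0. Among them were the windows of the glycine-rich protein genes GRP-3 (at least 122-fold higher window counts) and GRP3S (at least 82.2-fold), and of the aquaporin PIP2A (at least 21.8-fold). The lowest ratios were those of NHX8 (-1.55, SE 0.36), AT3G48640 (-1.48, SE 0.30) and AT1G11340 (-1.42, SE 0.38). Genes that rose had a raised window more often than other genes. Among 2659 genes tested together with their window, 1388 had a higher window. These were 308 of the 395 higher genes, where independent lists would give 206 (Fisher's exact test, odds ratio 3.88, p = 3.7e-30), and 343 of the 656 lower genes. The ratio has the gene's own count in its denominator. Here 209 of 392 higher genes had a higher ratio, where independent lists would give 207 (Fisher's exact test, odds ratio 1.02, p = 0.87). This odds ratio sets higher genes against lower and uncalled genes together. A higher ratio was found for 450 of the 656 lower genes and for 1401 of all 2647 genes. The ratio was thus more often higher where the gene fell, a difference that was not tested. WRKY70 itself fell by 1.04 on the log2 scale (SE 0.12) while its window rose. The count of lower ratios was 6 without Col-0 replicate 2, and the lower call of AT3G57700 (-1.39, SE 0.49) was lost in 5 of the 6 fits without 1 library.

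Assembled loci were also mostly higher. Of 5329 tested, 2708 were higher and 147 lower in xrn3-8, with a median log2 fold change of 1.12. XLOC_003850 and XLOC_007844 held 0 counts in Col-0 and 1050 and 939 in xrn3-8, at least 297-fold and 265-fold higher. Of the XLOC_007844 counts xrn3-8 replicate 2 held 590, and its log2 fold change of 11.17 was 10.43 without that library. XLOC_000917 and XLOC_005501 fell, with log2 fold changes of -2.67 (SE 0.22) and -2.49 (SE 0.15). The 2161 loci that are also in the xat table were all higher, but that subset appears to have been picked on these libraries. Their median log2 fold change was 3.46 and carries much of the median over all loci. Among the 3168 other loci, 547 were higher and 147 lower, with a median of 0.36. Taking out loci that were all raised biases this median downwards, so it is not free of that choice either. Scaled on themselves, 1470 loci were higher and 895 lower (62.2% instead of 94.9% of calls higher), and DESeq2 with its own size factors gave 2296 and 895 (72.0%).

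**Figure D2:**
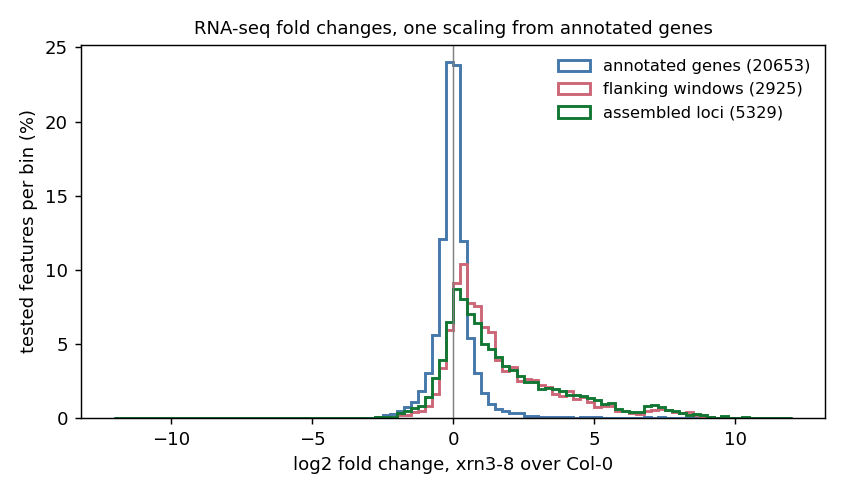
Distribution of RNA-seq log2 fold changes (horizontal axis, xrn3-8 over Col-0) as the percentage of tested features per bin of 0.25, for annotated genes, flanking windows and assembled loci under one scaling. Genes centre on 0, while windows and loci have medians of 1.05 and 1.12 and a long tail to the right. Loci that are also in the xat table appear to have been picked on these libraries. Without them the loci median is 0.36, which the removal of raised loci biases downwards.

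Of 20653 annotated genes tested by RNA-seq, 3289 were higher and 3593 lower in xrn3-8. With a change of at least 2-fold, 1107 were higher and 870 lower. The median Col-0 level was 0.358 CPM for these higher genes, 68 of which had 0 counts. It was 7.26 CPM for the lower genes and 8.43 CPM for all tested. A gene with few Col-0 counts passes the filter only where xrn3-8 counts are high, so it can hardly be called lower. All 68 tested genes with 0 Col-0 counts were among these higher genes, as this filter favours. These levels therefore do not show that silent genes rose more readily. AT2G41445 held 0 counts in Col-0 and 860 in xrn3-8, at least 243-fold higher, and ATSAC1B (AT5G66020), annotated as a phosphoinositide phosphatase, 0 and 496, at least 140-fold higher. AT2G06860, labelled a pseudogene, went from 1 to 1407 counts, a ratio of 1192 (95% interval 214 to 47128). The galactosidase gene BGAL14 went from 1 to 648, a ratio of 549 (98.2 to 21723). For both genes the Col-0 count lay in Col-0 replicate 2. NUDT24 went from 3 to 805 counts, a ratio of 227 (77.5 to 1105). AT2G13547 fell from 788 to 2 counts, a ratio of 0.00215 (0.00026 to 0.0078). COL2, a CONSTANS-like transcription factor gene, fell by 3.18 on the log2 scale (SE 0.14, adjusted p = 4.0e-07), AT1G13650 from 7.93 ± 1.42 to 0.308 ± 0.124 CPM and the purine permease gene PUP8 from 2.12 ± 0.183 to 0.119 ± 0.028 CPM. The chloroplast gene ATCG00950 had 9.39 ± 13.9 and 0.519 ± 0.197 CPM, a log2 fold change of -4.19 that was -1.39 without Col-0 replicate 2, and its adjusted p of 0.013 became 0.057 without xrn3-8 replicate 3. Genes labelled pseudogene in the reference were higher in 54 (28.1%) and lower in 15 of 192 tested, out of 3903 counted. Of protein-coding genes 15.9% were higher (Fisher's exact test, odds ratio 2.07, adjusted p = 4.6e-05 over 16 class tests), with 19781 of 27444 tested. The filter passes weakly expressed genes mainly where 1 group is high, and expression level was not in this test. The difference between the classes may therefore come from the filter. With total counts in place of TMM factors, the median of all genes moved by 0.16 on the log2 scale, and 5458 genes were higher and 2215 lower (71.1% instead of 47.8% of calls higher). Reads that run into a gene from a neighbour are counted in it, so a higher count is not by itself a transcript of that gene.

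Several lists fixed beforehand moved mostly one way. Nuclear photosynthesis genes were lower, with 17 of 21 past the threshold and 0 higher (20 lower adjusted over the list alone), a median log2 fold change of -0.70 and a camera adjusted p of 2.7e-12 over 15 lists (adjusted p = 0.26 with an estimated correlation). The light-harvesting gene LHCB2.1 fell from 1088 ± 70 to 491 ± 51 CPM and the Rubisco small subunit gene RBCS1B from 315 ± 16 to 181 ± 7.2 CPM. Jasmonate and wound genes were lower in 10 of 13 and higher in 0 (1 higher and 10 lower adjusted over the list alone, camera adjusted p = 6.4e-08, and 0.26 with an estimated correlation). The repressor JAZ9 fell from 274 ± 29 to 73.5 ± 2.2 CPM and the biosynthetic gene OPR3 from 183 ± 29 to 54.6 ± 7.0 CPM, while the wound markers VSP1 and VSP2 had log2 fold changes of 0.29 and 0.75 without passing. Salicylate and defence genes were lower in 9 and higher in 1 of 20 (1 higher and 10 lower adjusted over the list alone, camera adjusted p = 9.4e-07, and 0.26 with an estimated correlation). EDS1, a regulator of defence signalling, fell by 1.12 (SE 0.07) and the transcription factor gene WRKY33 by 1.27 (SE 0.08), and CYP71A13 of camalexin synthesis was the gene that rose (0.98, SE 0.34). No gene of this list was higher without Col-0 replicate 2, Col-0 replicate 3, xrn3-8 replicate 1 or xrn3-8 replicate 3. Dividing-cell markers were higher in 6 of 10 and lower in 0 (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0102, and 0.34 with an estimated correlation). Of these markers 3 were higher without Col-0 replicate 3, and 4 without Col-0 replicate 2, xrn3-8 replicate 2 or xrn3-8 replicate 3. The cytokinesis gene KNOLLE rose from 8.90 ± 0.60 to 16.6 ± 1.31 CPM and the cyclin gene CYCB1;2 from 7.38 ± 0.76 to 14.9 ± 1.59 CPM. The XRN family with FRY1 passed with 2 of 4 lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.0123, and 0.26 with an estimated correlation), but holds the mutated gene. None of these 5 calls held with an estimated correlation. With total counts the photosynthesis list had 13 lower and 0 higher.

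The circadian clock list moved in both directions, with 8 of 15 genes higher and 6 lower, the same adjusted over the list alone. The morning genes CCA1 and LHY, which encode related transcription factors, fell from 59.6 ± 7.98 to 11.6 ± 1.04 CPM and from 34.2 ± 5.70 to 6.80 ± 0.55 CPM. LNK2 fell from 142 ± 15.5 to 37.9 ± 4.9 CPM. TOC1, an evening gene, rose from 29.1 ± 1.03 to 77.8 ± 3.23 CPM. As a list it had no balance to one side (camera adjusted p = 0.93, median 0.60, fry direction down), while fry's test for change in either direction had an adjusted p = 0.00010. All 15 lists tested passed that last test, the highest at 0.043 for heat shock genes, so passing it is not particular to the clock.

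**Figure D3:**
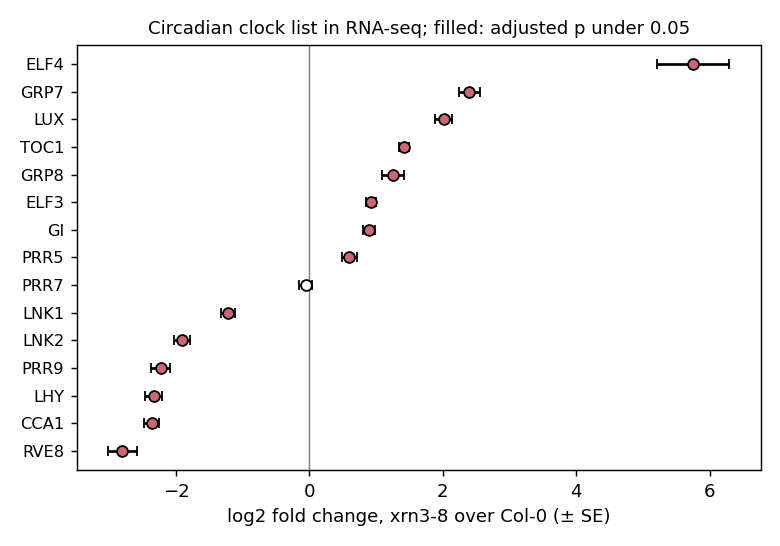
Log2 fold change of the 15 circadian clock genes in RNA-seq (horizontal axis, xrn3-8 over Col-0, whiskers ± SE, 3 libraries per group), one gene per line. Filled points passed the threshold: 8 lie to the right of 0 and 6 to the left, from ELF4 at 5.76 (7.28 without Col-0 replicate 1) to RVE8 at -2.80.

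The other lists did not pass with camera. Cold, drought and abscisic acid genes were higher in 11 and lower in 6 of 22 (12 and 6 adjusted over the list alone, camera adjusted p = 0.051). COR15A and COR15B, cold-induced chloroplast proteins, rose by 1.56 (SE 0.14) and 1.87 (SE 0.15), and RD29A by 1.88 (SE 0.18), while the transcription factor gene RD26 fell by 1.63 (SE 0.15). The adjusted p of this list was 0.029 with total counts and 0.26 with an estimated correlation. It ranged from 0.0091 without xrn3-8 replicate 2 to 0.127 without Col-0 replicate 2. RNA silencing genes were higher in 7 and lower in 1 of 21, the same adjusted over the list alone (camera adjusted p = 0.064, and 0.030 with total counts, where 12 were higher and 0 lower). AGO1 rose by 0.45 (SE 0.07), DCL2 by 0.53 (SE 0.09), RDR2 by 0.60 (SE 0.11) and NRPE1 by 0.46 (SE 0.09), and RDR1 fell by 0.27 (SE 0.07). Of 3′ end processing factors 5 of 20 were higher and 0 lower (2 and 0 adjusted over the list alone, adjusted p = 0.14), among them FY at 0.51 (SE 0.11) and FPA at 0.38 (SE 0.09). With total counts 11 of these factors were higher, and from 2 to 5 with 1 library left out, with 2 in 4 of the 6 fits. Of nuclear exosome genes 3 of 13 were higher and 0 lower (0 and 0 adjusted over the list alone, adjusted p = 0.93, median -0.09, mean 0.0013, median 0.06 with total counts). They were HEN2, RRP4 and RRP6L2, and 0 to 2 of the 13 passed without any single library. Phosphate starvation genes were lower in 2 of 9 and higher in 0, namely AT4 and SPX1, the same adjusted over the list alone (adjusted p = 0.33, median -0.10, and 0.05 with total counts). Flowering time genes were higher in 2 and lower in 1 of 12 (2 and 0 adjusted over the list alone, adjusted p = 0.93, median -0.07, camera direction up, median 0.09 with total counts). FLC, a repressor of flowering, rose by 0.88 (SE 0.18), while SVP at -0.21 no longer passed under 3 other scalings or in 5 of the 6 fits without 1 library. Without xrn3-8 replicate 2, 1 flowering time gene was higher and 3 were lower. Of heat shock genes HSP101 rose among 5 tested (adjusted p = 0.59), with its own adjusted p at 0.055 without Col-0 replicate 1 and 0.057 without Col-0 replicate 3. Of senescence markers ORE1 rose and WRKY6 and NYE1 fell among 5 (adjusted p = 0.59, median 0.06, camera direction down). Their median ranged from -0.15 to 0.38 with 1 library left out and was 0.23 with total counts, and camera's direction was up without Col-0 replicate 1. Of flower and seed markers PI rose from 30 to 432 counts among 3 (adjusted p = 0.72, median -1.31, mean 0.17). For these 3 lists the calls adjusted over the list alone were the same in number. Of the root markers, 1 was tested, too few for a list test.

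Genes next to a gene with a raised window were more often higher themselves. Neighbours on both sides were taken, as the side of the window is not given, so some do not lie on the window's side. Among 1159 neighbouring pairs at 500 to 2000 nt, the adjacent gene was higher in 27.3% where the window was higher and in 18.4% where it was not (Fisher's exact test, two-sided, odds ratio 1.66, 95% interval 1.25 to 2.23, p = 0.00036). With both changes at least 2-fold, the odds ratio was 2.62 (Fisher's exact test, 1.71 to 4.08, p = 1.8e-06). AT2G41445 lies next to AT2G41440 and AT2G41450, whose windows rose from 0 to 316 and from 13 to 194 counts. AT2G06860 lies next to the cell wall gene XTH4, whose window rose from 0 to 76 counts. AT4G20365, labelled a pseudogene (0 and 372 counts), lies next to RABE1b, whose window rose from 0 to 130 counts. PERK2 (0 and 218 counts) lies next to AT3G24420, whose window rose from 1 to 66. Genes are not replicates, so these p-values describe these libraries. The tests treated pairs as independent, although a gene or a window can recur among them. At gaps of 1000 to 2000 nt the odds ratio was 1.35 (Fisher's exact test, 0.87 to 2.11, p = 0.18), and over 2000 and up to 5000 nt it was 1.85 (Fisher's exact test, 1.06 to 3.33, p = 0.024, 503 pairs).

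Small RNA over genes changed mostly upwards in xrn3-8. Of 9048 genes tested, 562 were higher and 91 lower. XRN3 had the largest log2 fold change of those named, but without Col-0 replicate 2 it stood at 10.90, below AT1G65940 at 12.08. The transcribed pseudogene AT1G65940 went from 2 to 1633 counts, a ratio of 810 (95% interval 224 to 6691). Both Col-0 counts lay in Col-0 replicate 2, and its log2 fold change of 9.40 was 12.08 without that library and 8.81 without Col-0 replicate 1. AT4G16080 held 0 and 220 counts, at least 72.7-fold higher, AT1G04957 0 and 116, at least 38.3-fold higher, and CYTOSLEEPER (AT1G15300) 0 and 85, at least 28.1-fold higher. AT3G13830 fell from 39.7 ± 9.12 to 0.300 ± 0.134 CPM, AT5G07575 from 12.3 ± 2.64 to 0.410 ± 0.310 CPM and AT3G03945 from 7.70 ± 0.215 to 0.224 ± 0.269 CPM. AT1G61320 went from 128 to 2 counts, a ratio of 0.0155 (0.00186 to 0.0571), with both xrn3-8 counts in xrn3-8 replicate 1, and AT4G10603 from 158 to 3, a ratio of 0.0188 (0.00384 to 0.0560), with all 3 counts in xrn3-8 replicate 2. Without these libraries the log2 fold changes of AT1G61320 and AT4G10603 moved from -5.75 to -8.46 and from -5.56 to -8.73. That of AT3G03945 moved from -5.12 to -6.43 without xrn3-8 replicate 1 and to -4.52 without xrn3-8 replicate 3, and that of AT5G07575 from -4.86 to -5.65 without xrn3-8 replicate 2. Protein-coding genes gave 490 of the higher and 59 of the lower calls among 4399 tested. Small nuclear RNA genes were higher in 11 of 22 and lower in 0, against 11.1% of protein-coding genes higher (Fisher's exact test, odds ratio 7.97, adjusted p = 1.6e-05 over 16 class tests), but several are near-identical copies. Ribosomal RNA held 28.7% ± 3.15 of small RNA counts over genes in Col-0 and 17.8% ± 10.1 in xrn3-8, with 6.27% in xrn3-8 replicate 3. The counts of calls depend on single libraries: 288 higher and 37 lower without Col-0 replicate 1, 346 and 40 without Col-0 replicate 2, 300 and 37 without Col-0 replicate 3, 406 and 45 without xrn3-8 replicate 2, and 489 and 130 without xrn3-8 replicate 3.

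Over the xat loci, small RNA was higher for 200 and lower for 51 of 789 loci tested. XLOC_002149 held 0 counts in Col-0 and 719 in xrn3-8, at least 238-fold higher. XLOC_002355 was picked as the xat locus whose small RNA counts lay closest to those of XRN3 in the 6 libraries. It held 96.7% to 99.99% of the XRN3 small RNA count in each library, a match that this choice favours. Its position is not given in the sources used here, but it appears to repeat the XRN3 result. XLOC_008088 fell from 243 to 8 counts, of which xrn3-8 replicate 2 held 5. XLOC_007384 fell from 2640 to 252 counts, of which xrn3-8 replicate 3 held 168, and its log2 fold change of -3.46 was -4.33 without that library. With DESeq2 and its own size factors 221 were higher and 105 lower (67.8% instead of 79.7% of calls higher), and without xrn3-8 replicate 3, the library with 6.27% ribosomal RNA, 191 and 74.

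Genes with higher small RNA and genes with higher RNA overlapped about as often as independent lists. Among 3192 genes tested in both assays, 88 were higher in both where independent lists would give 95.6 (Fisher's exact test, odds ratio 0.89, 95% interval 0.68 to 1.14, p = 0.38). XRN3 belongs to the 94 genes with higher small RNA and lower RNA, whose number was not tested. Higher small RNA over genes and higher flanking windows gave an odds ratio of 0.97 (Fisher's exact test, 0.58 to 1.65, p = 0.90) over 835 genes. At the 578 xat loci tested in both assays, all higher in RNA-seq, small RNA was higher for 157 and lower for 30. Across these loci, which are not independent replicates, the fold changes had a Spearman's rho of -0.13 (permutation test, p = 0.0018) and a Pearson's r of -0.05. The assays used different plants of different age and medium.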

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

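The assembled loci, their alternatives, the strand-free neighbour test, the settings with nuclear genes, without XRN3 and with DESeq2 on the gene-table scaling, and total counts for the lists were chosen after the results were seen. Of the values that answer a comparison, 150 alternatives kept direction and side of the threshold or stayed within 1.5 times, 32 counts moved further and 1 association lost its call. Requiring 2-fold changes left 1107 genes higher and 870 lower. Total counts gave 5458 and 2215 genes, with a median shift of 0.16, and turned XRN2 to 0.091. Windows numbered 911 higher and 246 lower with DESeq2, 3412 higher with DESeq2 on the gene-table scaling, 3518 higher with no filter, and 671 and 347 scaled on themselves. Assembled loci numbered 895 lower with DESeq2, 4170 higher with DESeq2 on the gene-table scaling, 4785 higher with no filter, and 1470 and 895 scaled on themselves. Scaling features on themselves centres them by construction, and no filter tests more of them; the causes of the other shifts were not tested. Small RNA over genes gave 1039 higher and 184 lower with no filter, and xat loci 483 higher with no filter and 105 lower with DESeq2. Of 15 lists tested, 5 passed with camera's preset correlation, 0 with an estimated correlation and 8 with fry, which does not compare a list with other genes. These 8 include RNA silencing, cold with drought and abscisic acid, and phosphate starvation genes. At gaps of 1000 to 2000 nt the odds ratio was 1.35 (p = 0.18, Fisher's exact test), but over 2000 and up to 5000 nt, with 503 pairs, it was 1.85 (p = 0.024, Fisher's exact test). The cause was not tested.

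Without single libraries, lower ratios ranged from 6 to 15, and small RNA over genes from 288 to 489 higher and from 37 to 130 lower. The 288 came without Col-0 replicate 1, and the 37 came both without Col-0 replicate 1 and without Col-0 replicate 3. List counts also moved further: dividing-cell markers from 6 to 3 higher, 3′ end factors from 5 to 2, nuclear exosome genes from 3 to 0 and flowering time genes from 1 to 3 lower. Counts that stayed within 1.5 times were 2474 to 3267 genes higher, 1391 to 1997 windows higher, 2473 to 3356 loci higher and 191 to 235 xat loci higher. XRN3 RNA ranged from -1.30 to -1.19. Uncalled genes that turned sign were HSP70 (0.05, then -0.16 without Col-0 replicate 1 and -0.08 without xrn3-8 replicate 3, range -0.16 to 0.23) and HSFA2 (-0.27, then 0.23 without Col-0 replicate 2, range -0.72 to 0.23). Over 2058 comparisons of 166 named features, 67 lost and 13 gained a call, in 24 features. The replicate number as a block gave 167 higher and 24 lower for small RNA over genes and, in limma's fit of log ratios, 17 lower ratios against 16 without the block. It gave 3407 and 3874 genes, 1330 and 40 windows, 175 and 45 xat loci and 2522 and 131 assembled loci. Adjusted p with the block was 0.066 for AT1G04957 and 0.081 for CYTOSLEEPER in small RNA, and 0.016 for the cold, drought and abscisic acid list. Same-numbered libraries correlated at 0.06, 0.15 and 0.10 in RNA-seq and at -0.45, 0.04 and -0.16 in small RNA, so the numbers were not taken to pair the libraries. All 3 RNA-seq numbers had their own number as best partner, a hint from the data and not the design. In the simulation 2-fold changes were recovered for 9.64% of ratios. The data held far more called ratios, 1407 higher and 11 lower, so the adjusted threshold was less strict and recovery may have been higher. Missing calls there still do not show missing changes.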

Other observations

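All tests of explanations and gene classes below were chosen after the results were seen. The comparison with other splits was fixed before, except for assembled loci and neighbouring genes, whose tests were themselves chosen later. Small RNA over spliceosomal RNA genes was led by copies of U1, with log2 fold changes of 3.66 for U1.10 (SE 0.18), 2.95 for U1.4 (SE 0.21) and 2.66 for U1.5 (SE 0.23). The U4 genes U4.7 and U4.8 rose by 1.71 (SE 0.27) and 1.64 (SE 0.19), and U6-1 and U6.4, which hold identical counts, by 1.07 (SE 0.15). Transfer RNA genes were higher in 23 and lower in 0 of 353 (6.5%), less often than protein-coding genes (Fisher's exact test, odds ratio 0.556, adjusted p = 0.0081). Long noncoding RNA genes (2.9%), transcribed pseudogenes (2.6%), small nucleolar RNA genes (2.0%) and pseudogenes (0.51%) were higher less often still. Small nucleolar RNA windows were higher in 2 of 71 and lower in 0 (odds ratio 0.0263 against protein-coding windows, Fisher's exact test, adjusted p = 1.2e-18). Windows of pseudogenes (29.0%), long noncoding RNA genes (27.8%) and transcribed pseudogenes (17.1%) were also higher less often than protein-coding windows (52.5%). Of chloroplast genes in RNA-seq, 1 was higher and 3 were lower among 124.

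At 1209 genes more than 2000 nt from their neighbours, window counts followed the flanked gene, with Spearman's rho of 0.41 to 0.46 across genes in Col-0 libraries and 0.72 to 0.77 in xrn3-8 libraries. With the neighbours on either side rho was 0.10 to 0.15. Genes are not independent replicates. The summed windows of these genes held 30.4 to 32.3 CPM in Col-0 and 108 to 139.8 CPM in xrn3-8. Sparse counts can lower rho by themselves, so the higher rho in xrn3-8 does not show a closer tie of window and gene.

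Small RNA over XRN3 was high in each xrn3-8 library. Scaling is argued against by the raw counts, whose lowest xrn3-8 value was 682 times the highest in Col-0. Reads shared with the related genes are argued against as well, since XRN2 and XRN4 together held at most 0.0054% of the XRN3 count in any xrn3-8 library. A candidate explanation is small RNA made from a transcript that xrn3-8 plants have at this locus. XLOC_002355, picked for small RNA counts close to those of XRN3, had 343 RNA-seq counts in xrn3-8 and 0 in Col-0. But it is in the xat table, whose tested loci were all higher in RNA-seq, so this rise is not independent evidence. The explanation could not be decided, as the tables hold neither the position of XLOC_002355 nor its strand or sequence, and the RNA-seq plants were older.

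Clock genes moved in opposite directions. All 14 called clock genes kept sign and call under total counts, median-of-ratios factors and nuclear genes only, against scaling as the cause. Of them 6 were lower, which added reads from a neighbour cannot produce. For the 8 that rose, reads running into the gene from a neighbour could not be decided. Among their 16 adjacent genes only 1 had a window that could be tested, and that window was not called higher. The other adjacent genes had no window or one that failed the filter. Genes taken as morning genes had a median of -2.28 (6 genes) and those taken as evening genes 1.34 (8 genes), a difference of 3.62. The phases were assigned after the directions were seen, and PRR7, which was not called, was left out, so this difference restates the pattern and supports no explanation. A shift of clock phase, from the hour of harvest or from the genotype, stays open, since the labels give no hour, and photosynthesis and jasmonate genes may follow the hour too, which was not tested.

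Genes at least 2-fold higher lay beside genes with raised windows more often than beside genes with other windows. The odds ratio was 4.27 (2.21 to 8.82) at gaps from 500 nt to under 1000 nt and 1.67 (0.94 to 3.04) at 1000 to 2000 nt, and the odds ratios differed (Zelen's exact test on 1159 pairs, p = 0.035). This is what reads running on between neighbours, in either direction, would give. But at gaps over 2000 and up to 5000 nt the odds ratio was 2.30 (0.88 to 7.10), and 1.85 (1.06 to 3.33) without the 2-fold bound. A steady fall with distance was thus not shown. The expression level of either gene did not account for it, as the odds ratio with both Col-0 levels in the model was 2.88 with a lower 95% bound of 1.66. Strand and the side of the window were not used, so the test cannot tell from which gene of a pair such reads would come. Pairs that share a gene or window were treated as independent. A shared response of neighbours stays open and untested.

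Of the 10 splits of the 6 libraries of an assay into 3 and 3, 1 is the real one, so a share under 0.1 cannot be had. Each other split mixes the genotypes in both of its groups. A genotype difference then widens the spread within groups, which can lower the counts of called features. The counts of the other splits are therefore no baseline for chance. The real split gave 6882 genes, 1488 windows, 1418 ratios, 653 genes in small RNA, 251 xat loci and 2855 assembled loci, and the highest of the other splits 0 each with edgeR. At an unadjusted p under 0.05 the real split gave 8925, 1626, 1543, 1515, 295 and 3095, and the highest other splits 381, 31, 35, 845, 32 and 55. The real split gave 5 gene lists with camera and the highest other split 4. For neighbouring genes no odds ratio could be formed in the other splits.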
